A study of Homo sapiens with 8 samples.

How the data were processed

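RNA abundance was measured in HK-2 cells, an established human proximal tubule cell line, on 8 Agilent 1-colour human gene expression arrays. Per the labels, cells were grown to confluence, deprived of serum for 24 h and kept in 30 mM glucose, and RNA was taken after 24 h with 0.5 µM canagliflozin or without it. The labels gave 4 canagliflozin and 4 control samples. They did not say whether the 4 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

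The deposited scanner files of the 8 samples held fluorescence intensity values in the Cy3 channel, as background-subtracted and detrended signal, raw mean signal and local background, with quality flags for each spot. Per the file headers, these were made with Feature Extraction 9.5.3.1 with background subtraction method 7 and spatial and multiplicative detrending. No normalization between arrays had been applied to them. The deposited value table of the series held log2 values for 17985 probes. Its background correction, offset and normalization were not given in the sources used here. The column medians of that table were 8.16, 8.163, 8.186 and 8.197 for canagliflozin replicates 1 to 4 and 8.177, 8.187, 8.19 and 8.186 for control replicates 1 to 4. Each column correlated most strongly, across probes, with the array of its own label, after each probe's mean was removed.

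The arrays lay on 2 slides of 4, each read in a scan of its own. Slide 1 held control replicates 1 and 2 and canagliflozin replicates 1 and 2, and slide 2 held replicates 3 and 4 of both groups. On both slides the controls took the first positions and the canagliflozin samples the last, so position on the slide and group cannot be separated.

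The background-subtracted signal was the starting point. The 1377 control spots were left out, which left 43118 spots for 34127 probes, of which 999 were printed in 10 copies. Each array was divided by its own 75th percentile and put on the log2 scale. The signal held values at or below 0, so a floor of 0.0470 was placed under the scaled signal, which is −4.41 on the log2 scale. This floor was chosen after the data were seen. Copies of a probe were averaged. A probe was kept when it was marked well above background on at least 4 of the 8 arrays, without regard to group, which kept 18063 probes. For each gene name the probe with the highest mean over all arrays was used, giving 14490 genes, of which 12991 were well above background on all 8 arrays. All levels and differences are therefore on the log2 scale relative to the 75th percentile of the array. Gene names are those of the files. Of the probes, 26377 matched a RefSeq gene table of assembly GRCh38.p14, used for names only, and 1974 of these had a different current symbol. Probe coordinates are those of the files, on genome build hg19, and no genome sequence was used.

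Array brightness set the depth. The 75th percentile of the signal was 398, 372, 255 and 219 intensity units for canagliflozin replicates 1 to 4 and 433, 332, 389 and 454 for control replicates 1 to 4. Between 51.9% and 58.2% of spots on an array were well above background. The number of arrays limits the precision, and the median residual SD of a gene was 0.22.

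Groups were compared with the moderated test of limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the package data.table at version 1.17.8 for reading, and Benjamini-Hochberg adjustment over all genes at 0.05. Gene lists and cell type marker lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists tested. Camera with an estimated correlation and fry were run beside it. The test, the filter, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined, apart from the floor and the additions stated here. Because the slides were found to differ, limma fits within each slide and a test of the slide by treatment difference in fold change were given as well. The within-slide fits had been planned, and the test of the difference was added after the data were seen. On simulated data of the same size, the comparison of 4 with 4 found 74.6% of genes changed 2-fold, 24.8% of those changed 1.5-fold and 0.0434% of unchanged genes. The test of the difference found 24.6% of 2-fold differences and 0.0140% of unchanged genes. The simulated genes were independent of each other and had no slide effect beyond the changes put in. These rates may therefore not hold for the real arrays.

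The named genes are those past the adjusted threshold whose groups did not overlap, up to 12 in each direction, and where fewer than 5 passed in a direction, the 8 with the smallest p. To these were added SLC5A1, SLC5A2, TNFRSF1A, IL6, MMP7 and FN1 in every case, and up to 4 passing members of each list, or up to 2 where none passed. Features without a gene symbol were not named, and some genes that the rules name are not reported here. Added after the data were seen were the 12 genes with the largest slide difference in each direction among those past the threshold that had opposite directions on the slides, no overlap between the groups within either slide and signal well above background on all 8 arrays.

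The alternatives were scaling by the array median, quantile normalization, normexp background correction with offset 50 on the raw signal, the deposited log2 value table, no filter or a filter on all 8 arrays, the mean of a gene's probes, slide or replicate number as a block, each slide alone, a trended and robust variance, spots marked as outliers set to missing, leaving out each array, other list tests, a 1.5-fold threshold and an adjusted threshold of 0.1. Floors at 0.5 and 2 times the main floor and removal of the trend with probe GC content in 12 bins were added after the data were seen. Every one of the 35 ways to split the 8 arrays into 4 and 4 was also fitted. No array was left out of the main comparison.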

Results

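Transcript levels were measured in HK-2 cells, a line of human proximal tubule origin, kept in 30 mM glucose and given 0.5 µM canagliflozin, an inhibitor of the sodium-glucose cotransporter SGLT2, or left untreated. Each group held 4 arrays, 2 on each of 2 slides. Of the 14490 genes tested, 12991 were well above background on every array. The 75th percentile of the signal was 311 ± 87.4 intensity units in canagliflozin (SD, n = 4) and 402 ± 53.9 in control (SD, n = 4). The correlation of log2 levels across genes was between 0.973 and 0.996 for every pair of arrays, and no array was a copy of another. Canagliflozin replicates 1 and 2 correlated at 0.978 to 0.984 with canagliflozin replicates 3 and 4. With control replicates 3 and 4 they correlated at 0.986 to 0.990. The other arrays showed no such crossing. Control replicate 2 correlated at 0.991 and 0.992 with control replicates 3 and 4, and at 0.992 and 0.989 with canagliflozin replicates 3 and 4. Canagliflozin replicates 3 and 4 correlated at 0.987 to 0.993 with control replicates 3 and 4. Control replicate 1, on slide 1, correlated at only 0.973 to 0.984 with every other array.

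The comparison of canagliflozin with control asked which transcripts differed after 24 h of SGLT2 inhibition in high glucose. A single gene passed the adjusted threshold. The signal of the probe for ANKRD36, which encodes an ankyrin repeat protein of a family with several near copies in the genome, fell by 1.20 on the log2 scale (SE 0.13, adjusted p = 0.0377). Its level was −2.13 ± 0.13 in canagliflozin (SD, n = 4) and −0.93 ± 0.17 in control (SD, n = 4), and all 4 canagliflozin values lay below all 4 control values. The difference was −1.29 on slide 1 and −1.10 on slide 2. Its probe, A_33_P3335030, lies on chromosome 2 at 97871812 to 97871870, and whether it also detects other copies was not checked here. The other probes for ANKRD36 gave −0.25 and −0.91, and ANKRD36BP2, a related copy, had a log2 fold change of −0.80 that did not pass (adjusted p = 0.158). With slide as a block in limma, the adjusted p of ANKRD36 was 0.0597 and no gene passed, although 1352 genes had an unadjusted p under 0.05. Leaving out any array but canagliflozin replicate 3 also ended the call, with an adjusted p of ANKRD36 between 0.0676 and 0.269.

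At an unadjusted p under 0.05, limma listed 235 genes as higher and 957 as lower with canagliflozin, against 724.5 expected by chance in all. With normexp background correction there were 36 and 361, fewer than expected by chance. In the main setting the real split gave 1192 genes at that p, and the other splits into 4 and 4 gave 23 to 4193. Slide 1 against slide 2, which also differ in scan, gave 1398. Of the splits with 2 arrays of each slide on either side, some gave more than the real split, with 1324, 1518, 1976 and 4193. The 4193 came with the groups exchanged on slide 2, and the fewest were 23. The count therefore does not exclude chance. The groups did not overlap in 783 genes, which is 5.40% of those tested. Chance gives 2.86% on average, and the overlap was not counted for other splits. Among the genes that did not pass, the smallest p-values on the lower side belonged to HYDIN, FOSB, SYT1, GOLGA6C, OTX1, SGSM2 and ANKRD36BP2. FOSB, a subunit of the AP-1 transcription factor (probe A_23_P429998, chromosome 19, 45978205 to 45978264), was at −3.53 ± 0.30 in canagliflozin and −2.42 ± 0.19 in control (SD, n = 4 each), a log2 fold change of −1.11 (SE 0.17, adjusted p = 0.156). It was −1.05 on slide 1 and −1.16 on slide 2, and the probe was well above background on 3 of the 4 canagliflozin arrays. SYT1, a calcium sensor of vesicle release (chromosome 12, 79843822 to 79843881), was at −2.06 ± 0.14 against −1.15 ± 0.25 in control, a log2 fold change of −0.91 (SE 0.15, adjusted p = 0.158). OTX1, a homeobox transcription factor, had a log2 fold change of −0.84, with −0.77 on slide 1 and −0.91 on slide 2. HYDIN, a protein of motile cilia, had −1.07 and GOLGA6C, a golgin of a family with near copies, −1.25, and HYDIN was well above background on 1 of 4 canagliflozin arrays and GOLGA6C on 3 of 4. An array of HYDIN lay at the floor, and its log2 fold change was −0.24 with the floor at 2 times its value. SGSM2 gave −0.83 with the probe used and 0.13 with its other probe.

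On the higher side no gene passed, and the smallest p-values belonged to ZSCAN2, SRC, TTC16, SCD, NMNAT1, AP1S1, ZNF501 and IGSF9. SRC, a tyrosine kinase (probe A_23_P308603, chromosome 20, 36033496 to 36033555), was at 0.12 ± 0.10 in canagliflozin and −0.44 ± 0.23 in control (SD, n = 4 each), a log2 fold change of 0.56 (SE 0.14, adjusted p = 0.295). It was 0.69 on slide 1 and 0.43 on slide 2. SCD, the desaturase that makes monounsaturated fatty acids (chromosome 10, 102123917 to 102123976), was at 0.07 ± 0.23 against −0.60 ± 0.31, a log2 fold change of 0.67 (SE 0.18, adjusted p = 0.331), with 0.80 on slide 1 and 0.54 on slide 2. The log2 fold changes of ZSCAN2, TTC16, AP1S1, ZNF501 and IGSF9 were 0.75, 0.79, 0.37, 0.42 and 0.40. NMNAT1, an enzyme of nuclear NAD synthesis, gave 0.89 with the probe used and −0.16 and −0.02 with its other probes.

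**Figure D1:**
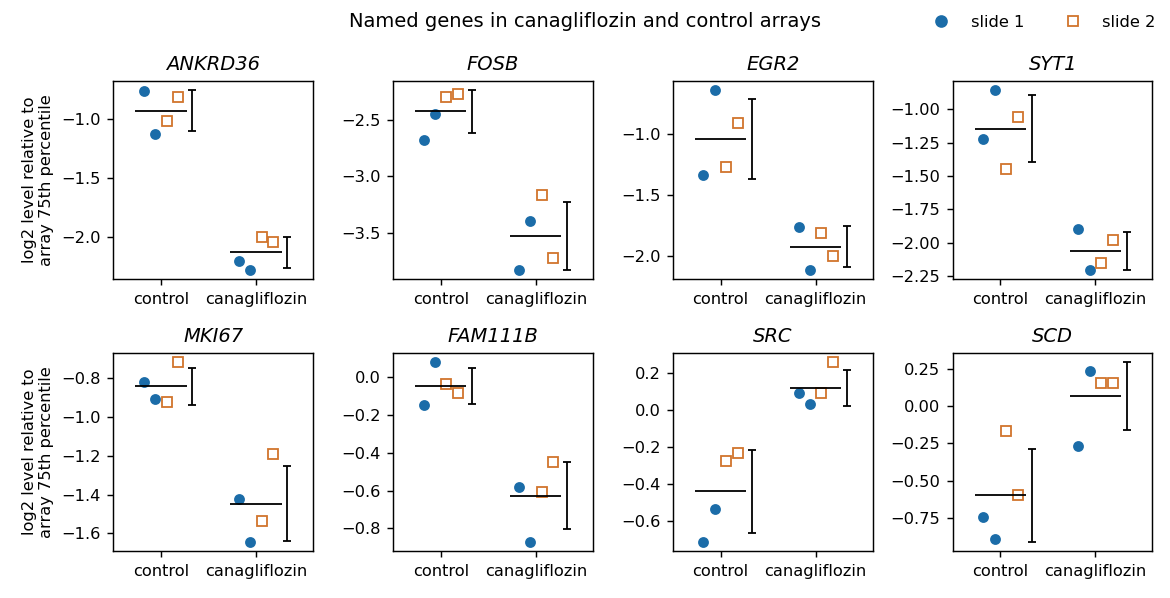
Level of 8 named genes on each array (vertical axis, log2 relative to the 75th percentile of the array), by group, with circles for slide 1, squares for slide 2, a line at the group mean and a bar of 1 SD to each side. ANKRD36 lay at −2.13 ± 0.13 in canagliflozin and −0.93 ± 0.17 in control, and the other 7 genes did not pass the adjusted threshold.

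Of the targets of the drug, SLC5A2, which encodes SGLT2 (chromosome 16, 31502023 to 31502082), was dim, at −2.63 ± 0.48 in canagliflozin and −3.04 ± 0.34 in control (SD, n = 4 each), a log2 fold change of 0.40 (SE 0.25, adjusted p = 0.655). SLC5A1, which encodes SGLT1, was well above background on 0 of 8 arrays and was not tested. None of the inflammation and fibrosis readouts passed. TNFRSF1A, a TNF receptor, had a log2 fold change of 0.10 (SE 0.14, adjusted p = 0.855), the cytokine IL6 had −0.16 (SE 0.17, adjusted p = 0.792) and the matrix protease MMP7 had 0.21 (SE 0.18, adjusted p = 0.739). FN1, the matrix protein fibronectin, had −0.28 (SE 0.16, adjusted p = 0.647), made up of −0.65 on slide 1 and 0.09 on slide 2.

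Gene lists were compared with all other genes. The cytosolic ribosomal proteins were higher with canagliflozin by the test at the preset correlation, with a positive log2 fold change in 57 of 58 measured genes and a median of 0.17 (adjusted p = 5.12e-08). This call was lost with an estimated correlation (adjusted p = 0.788), and fry, which compares the list with no change and not with other genes, gave an adjusted p of 0.852. The median stayed above 0 but fell to 0.015 after quantile normalization and to 0.0043 in the deposited value table, where 37 and 30 of 58 were positive. It was 0.059 without canagliflozin replicate 4 and 0.11 without control replicate 1. RPS16 and RPL8, subunits of the small and the large ribosomal particle, had log2 fold changes of 0.26 each, and no single member passed. The list's median was −0.0018 on slide 1 (adjusted p = 0.380) and 0.35 on slide 2 (adjusted p = 3.07e-10), where it was −0.00011 after quantile normalization and −0.017 in the value table, and with slide as a block the list passed at 3.45e-09. No other list passed at the preset correlation, and no member of any list passed over all genes.

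Immediate early genes, which respond to growth factor signals within minutes, had negative log2 fold changes in 17 of 27 members, with a median of −0.10 and a mean of −0.19 (adjusted p = 0.0692, and 0.583 with an estimated correlation), while fry, which asks whether the members move one way, gave an adjusted p of 0.0170. FOSB and EGR2 passed when adjusted over the list alone (adjusted p = 0.00145 and 0.00519). EGR2, a zinc finger transcription factor (chromosome 10, 64571850 to 64571909), was at −1.92 ± 0.16 in canagliflozin and −1.04 ± 0.33 in control (SD, n = 4 each), a log2 fold change of −0.88 (SE 0.17, adjusted p = 0.192 over all genes), with −0.95 on slide 1 and −0.81 on slide 2. The list's median was −0.29 on slide 1 and −0.12 on slide 2, and −0.025 over all arrays with normexp background correction.

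Genes of S phase and DNA replication had negative values in 25 of 39 members, with a median of −0.092 (adjusted p = 0.0819), and −0.059 on slide 1 and −0.18 on slide 2, where the slide 1 median was 0.026 in the value table and 0.069 after removal of the trend with probe GC content. FAM111B, a protease, had −0.58 (SE 0.13, adjusted p = 0.221 over all genes) and passed when adjusted over the list alone (adjusted p = 0.0340). In the G2/M list 18 of 36 members were negative, with a median of −0.0078 (adjusted p = 0.488). There the proliferation marker MKI67 had −0.61 (SE 0.13, adjusted p = 0.203 over all genes and 0.0277 over the list alone), with −0.39 and 0.09 from its other probes, and CENPF had −0.62, with −0.50 from its other probe. The replication-dependent histones were negative in 18 of 20 genes, with a median of −0.14 (adjusted p = 0.123), as in HIST1H1D with −0.42 and HIST1H1E with −0.26. The p53 and apoptosis list had a median of −0.045 (adjusted p = 0.488), with −0.49 for BCL2L11 and −0.42 for PMAIP1. The other probes of BCL2L11 gave −0.06 and 0.31.

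Lists of energy metabolism did not pass. Respiratory complex I had 25 of 38 genes positive with a median of 0.041 (adjusted p = 0.0912), and complexes II to V had 27 of 39 positive with a median of 0.059 (adjusted p = 0.0819), which was −0.0021 after quantile normalization. NDUFB11 had 0.30, ATP5A1 0.25 and UQCRC1 0.27. Glycolysis had 13 of 22 positive with a median of 0.12 (adjusted p = 0.124), where LDHA had 0.31, with 0.20 from its other probe, and PFKL −0.99. The tricarboxylic acid cycle list had a median of 0.071 (adjusted p = 0.253), with 0.72 for IDH3B, whose other probe gave 0.28, and 0.25 for SUCLA2. Fatty acid oxidation and ketone genes had a median of 0.020 (adjusted p = 0.488), with 0.30 for ACSL1 and −0.26 for ACADM. In the list of glucose-responsive targets of MondoA and ChREBP 7 of 9 were negative with a median of −0.092 (adjusted p = 0.427), with −0.32 for KLF10 and −0.28 for TXNIP. The glucose transporter and proximal tubule list was split 12 to 10 with a median of 0.011 (adjusted p = 0.848), with 0.59 for GGT1 and −0.32 for SLC4A4. The other probe of GGT1 gave 0.29, from 1.16 on slide 1 and −0.59 on slide 2. Hypoxia targets had a median of −0.036 (adjusted p = 0.780), with −0.51 for VEGFA, whose other probe gave −0.08, and −0.36 for PPFIA4, which had 0.07 with normexp background correction.

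Sterol and lipid lists were near 0 over all 8 arrays. Cholesterol synthesis and uptake had a median of 0.023 (adjusted p = 0.488), with 0.12 for TMEM97 and 0.20 for HMGCS1. Fatty acid synthesis had a median of −0.016 and a negative mean, while its test, which compares the list with other genes, pointed up (adjusted p = 0.780), and its members SCD and ACACB had 0.67 and −0.33.

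Stress lists gave small medians. These were 0.059 for the integrated stress response (adjusted p = 0.253), with −0.31 for CEBPG and −0.26 for CTH, and 0.070 for autophagy and lysosome (adjusted p = 0.106), with 0.32 each for HEXA and ATP6V0D1. The metallothionein and metal list had 10 of 12 positive with a median of 0.12 (adjusted p = 0.124), with −0.33 for MTF1 and 0.48 for SLC39A10. Its median was 0.067 after quantile normalization and 0.044 in the deposited value table. Heat shock had a median of 0.058 (adjusted p = 0.388), with −0.35 for HSPH1, whose other probe gave −0.33, and 0.21 for DNAJB1. NRF2 targets had a median of −0.017, a mean of 0.0045 and a test pointing up (adjusted p = 0.639), with −0.48 for GCLM and −0.32 for GCLC, the subunits of the rate-limiting enzyme of glutathione synthesis. The unfolded protein response had a median of −0.041 and a test pointing up (adjusted p = 0.895), with −0.30 for SEL1L, whose other probe gave −0.07, and 0.24 for CRELD1.

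Among inflammation, matrix and injury lists, the TGF-beta response had 23 of 27 negative with a median of −0.12 (adjusted p = 0.133), with −0.25 for ID2, whose other probe gave −0.46, and −0.33 for TGFBR1 (adjusted p = 0.629), which was well above background on 0 of the 4 canagliflozin arrays and had 0.16 with normexp background correction. Inflammatory and NF-kB targets had a median of −0.044 (adjusted p = 0.677), with −0.69 for CXCL2, whose other probe gave −0.16, and −0.56 for BIRC3. Type I interferon genes had −0.073 (adjusted p = 0.749), with −0.31 for IFIH1 and −0.40 for USP18. Extracellular matrix genes were negative in 28 of 40 with a median of −0.040 (adjusted p = 0.488). LAMA5 had −0.62 and LAMA3 −0.41 there, and their other probes gave −0.17 and 0.09. The slides were opposed in both of these other probes, with 0.35 on slide 1 and −0.69 on slide 2 for LAMA5 and 0.26 and −0.08 for LAMA3. Metalloproteinases and their inhibitors had a median of 0.040 (adjusted p = 0.208), with 0.24 for SERPINE2 and 0.37 for MMP15. The slides were opposed for MMP15, with 0.88 on slide 1 and −0.14 on slide 2. Tubular injury genes had a median of 0.034 (adjusted p = 0.185), with 0.33 for KRT8, whose other probes gave 0.17 and 0.43, and 0.22 for S100A6. The KRT8 probes differed within the slides. The one with 0.43 gave 1.66 on slide 1 and −0.80 on slide 2, and the one with 0.17 gave −0.07 and 0.41.

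Marker lists of other cell types did not pass either. The podocyte list of 5 had a median of 0.0012 (adjusted p = 0.488), with 0.38 for CLIC5 and −0.29 for PODXL. The leukocyte list of 6 had 0.060 (adjusted p = 0.589), with 0.43 for CD68 and −0.48 for TYROBP. The fibroblast and pericyte list of 11 had −0.017 with a test pointing up (adjusted p = 0.848), with 0.20 for DES and −0.25 for COL1A1. Too few members were measured to test markers of other renal epithelium (3 of 14), endothelium (2 of 11) and keratinocytes (2 of 9).

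**Figure D2:**
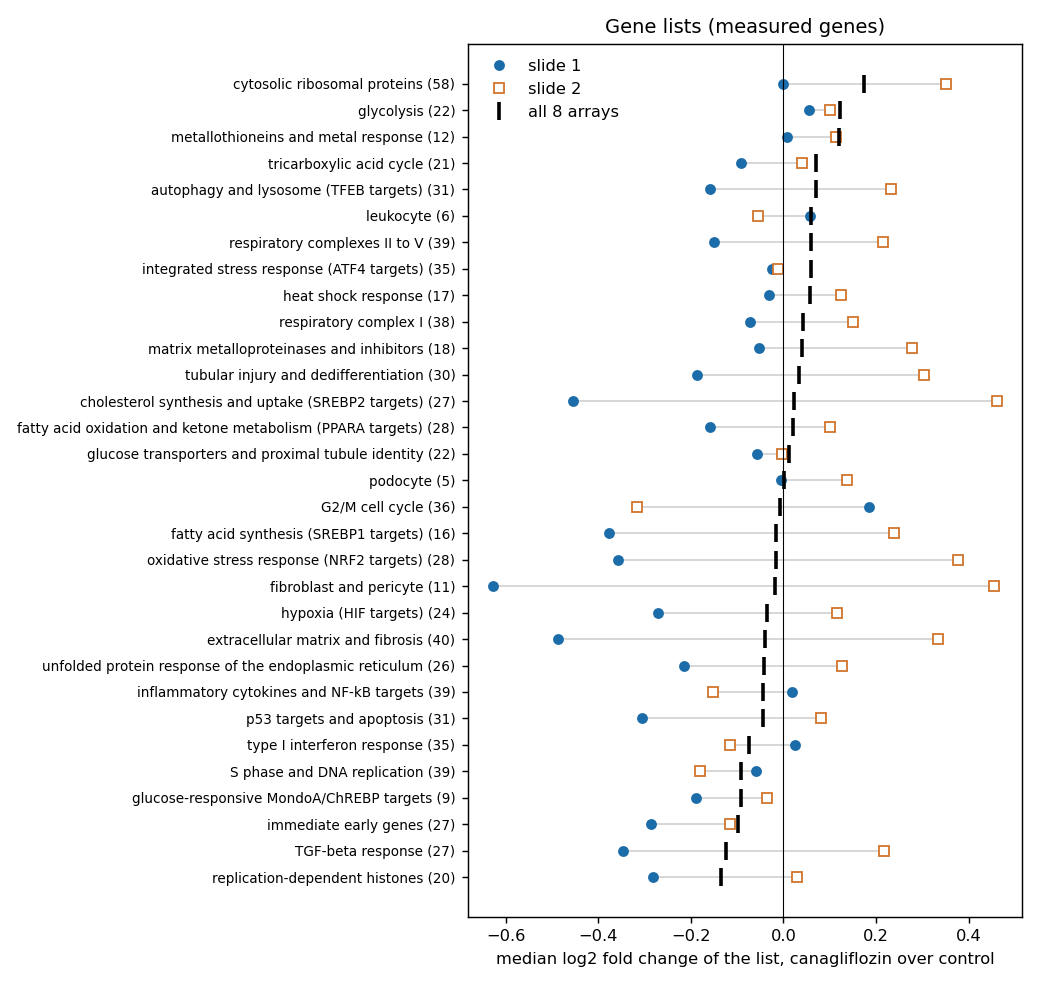
Median log2 fold change of canagliflozin over control (horizontal axis) for the measured genes of each of the 31 lists (number of genes in brackets), with circles for slide 1, squares for slide 2 and bars for all 8 arrays. The cholesterol list lay at −0.45 on slide 1 and 0.46 on slide 2, and 24 of the 31 lists had medians of opposite sign on the slides.

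The same comparison was made within each slide, 2 arrays against 2, to ask whether the difference held on both. The slides gave opposite differences for many genes. Log2 fold changes were positive in 3 of 27 cholesterol genes on slide 1 and in 27 of 27 on slide 2, in 3 and 34 of 40 matrix genes, in 1 and 11 of 11 fibroblast and pericyte markers, and in 22 and 0 of 36 G2/M genes. The slide difference of these 4 lists passed at the preset correlation but was lost with an estimated correlation (adjusted p = 0.805 to 0.864). In the G2/M list MKI67 and CENPF had negative values on slide 1, −0.67 and −0.86. The slide by treatment difference passed in 3568 of 14490 genes, higher on slide 2 in 1966 and lower in 1602, and the fold changes of 3416 of them had opposite directions on the slides. Across genes, which are not independent replicates, the fold changes of the slides had Pearson's r = −0.327 and Spearman's rho = −0.308. On slide 1 alone 1680 genes passed, 970 higher and 710 lower, and 1280 of these had the opposite direction on slide 2. With median scaling the balance on slide 1 turned to 1148 higher and 1630 lower, and 0 genes passed there with the floor at 2 times its value or with normexp background correction. On slide 2 alone limma called 0 genes, with 2880 at an unadjusted p under 0.05.

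RHOJ, a small GTPase (chromosome 14, 63757601 to 63757660), had a log2 fold change of −1.25 on slide 1 and 1.32 on slide 2, a difference of 2.58 (SE 0.36, adjusted p = 0.0088). The growth factor BMP4 had −1.09 and 0.92 and the microfibril protein MFAP4 −1.14 and 0.68. In the other direction, INHBE, an inhibin beta subunit induced by stress of the endoplasmic reticulum (chromosome 12, 57850864 to 57850923), had 1.64 on slide 1 and −0.68 on slide 2, a difference of −2.32 (SE 0.20, adjusted p = 0.00765). The mitotic kinase AURKB had 1.39 and −0.91, and the p38 kinase MAPK13 1.41 and −0.72. FN1 differed by 0.74 (SE 0.17, adjusted p = 0.0206) and HMGCS1, the synthase at the entry to the mevalonate pathway, by 0.99 (adjusted p = 0.0213), with −0.30 on slide 1 and 0.70 on slide 2. Signs on slide 1 and slide 2 were also opposite for CD68 (0.99 and −0.13), DNAJB1 (0.55 and −0.13) and COL1A1 (−0.69 and 0.18). With slide 2 nearer 0, so were those of TNFRSF1A (0.28 and −0.08), SLC4A4 (−0.70 and 0.06), GCLC (−0.66 and 0.03) and UQCRC1 (0.56 and −0.01). Among these, the slide difference passed in DNAJB1, SLC4A4 and GCLC (adjusted p = 0.0197, 0.0250 and 0.0283). The log2 fold changes of ANKRD36, FOSB, EGR2, SYT1, SRC and SCD had the same direction on both slides. MKI67 did so with the probe used, while another of its probes gave 1.45 on slide 1 and −1.26 on slide 2.

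By list, the slide difference passed in 9 of 31 at the preset correlation and in 0 with an estimated correlation, where adjusted p lay between 0.805 and 0.864 for these 9. The median differences relate to a median of 0.16 over all genes. Cholesterol synthesis and uptake had a median difference of 0.95 (adjusted p = 5.58e-06), with 20 of 27 members passing as higher on slide 2 and 0 as lower. Extracellular matrix had 0.74 (adjusted p = 3.57e-05), with 22 of 40 passing as higher and 1 as lower, and the fibroblast and pericyte markers had 1.22 (adjusted p = 0.00213), with 8 of 11 higher. The G2/M list had −0.44 (adjusted p = 4.59e-06), with 13 of 36 lower on slide 2 and 0 higher. NRF2 targets had 0.60 (adjusted p = 0.00152), the TGF-beta response 0.53 (adjusted p = 0.0123) and fatty acid synthesis 0.39 (adjusted p = 0.0247). S phase genes had −0.059 with a mean of −0.27 (adjusted p = 0.00916), and a median of −0.25 after quantile normalization, and the integrated stress response had a median of 0.026 but a mean of −0.22, with a test pointing down (adjusted p = 0.0367), and its median difference was −0.17 after quantile normalization. With normexp background correction the slide difference passed in 0 genes, with 2078 at an unadjusted p under 0.05, and 96.5% of the 3568 genes kept the sign of their difference. Fewer genes passed when any 1 canagliflozin array, or control replicate 3 or 4, was left out. Such a fit leaves 1 array of a group on a slide, so the other arrays supply its spread, and its counts are not given.

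**Figure D3:**
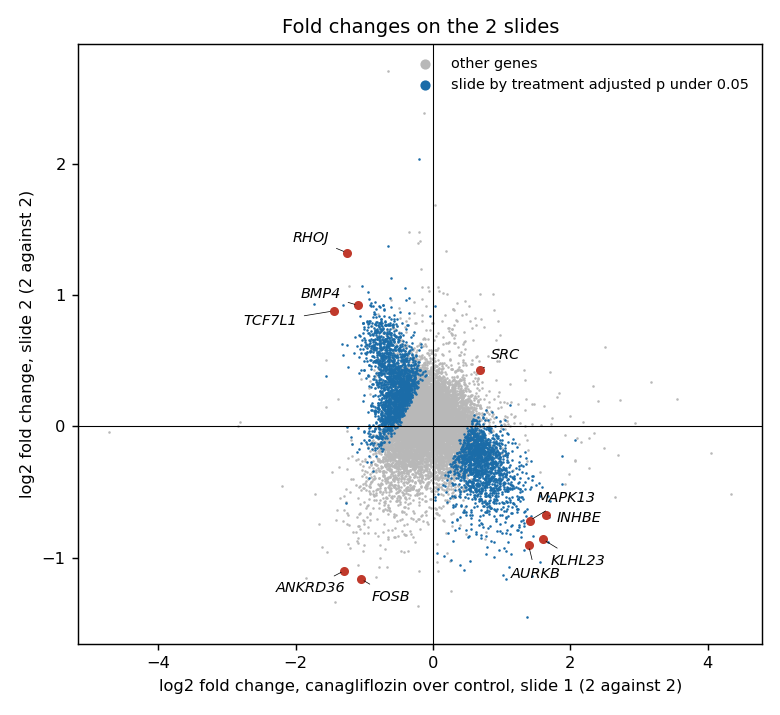
Log2 fold change of canagliflozin over control on slide 1 (horizontal axis) and slide 2 (vertical axis), 2 arrays against 2 on each, with 1 point for each of the 14490 genes and blue points for the 3568 with a slide by treatment difference. RHOJ, BMP4 and TCF7L1 were lower on slide 1 and higher on slide 2, INHBE, KLHL23, AURKB and MAPK13 the other way, and ANKRD36 and FOSB were negative on both.

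**Figure D4:**
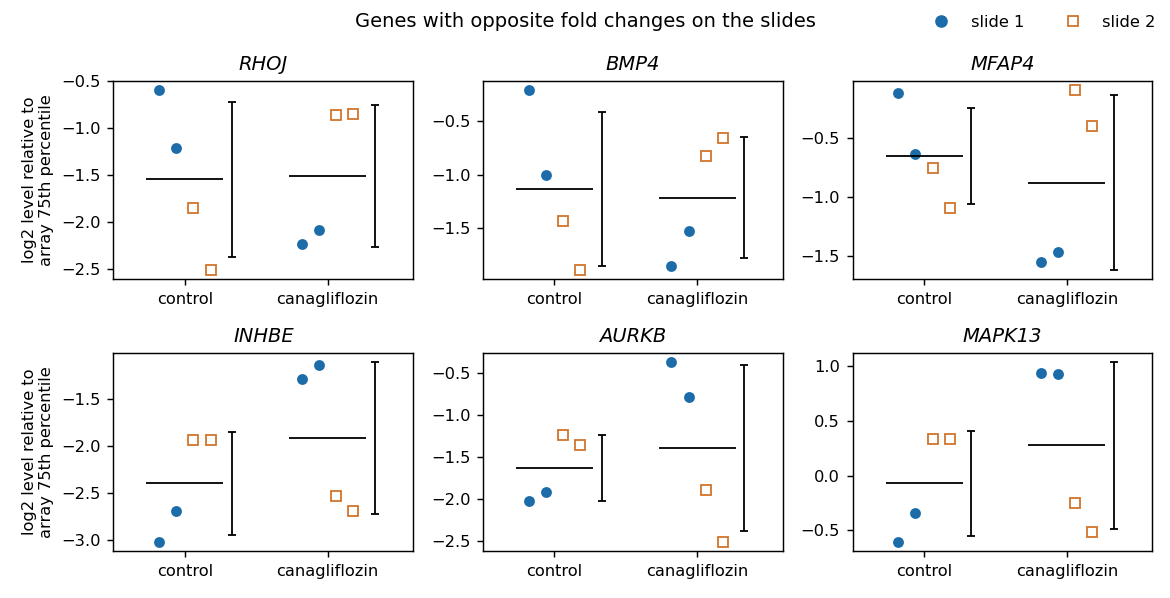
Level of 6 genes with a slide by treatment difference on each array (vertical axis, log2 relative to the 75th percentile of the array), by group, with circles for slide 1, squares for slide 2, a line at the group mean and a bar of 1 SD to each side. On slide 1 the canagliflozin arrays lay below the controls for RHOJ, BMP4 and MFAP4 and above them for INHBE, AURKB and MAPK13, and on slide 2 the order was the reverse.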

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

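The test of the slide by treatment difference, its gene and list values, the weighing of array brightness and scaling by quantile normalization, the removal of the trend with probe GC content and the count of splits balanced over the slides were chosen after the result or the data had been seen.

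Fold changes on the slides ran in opposite directions, with a slide by treatment difference in 3568 genes and in 0 with normexp background correction. The number of 3568 fell without some arrays and rose without others. Such a fit leaves 1 array of a group on a slide, so its counts are not given. The data argue against array brightness and scaling as the whole cause, since quantile normalization left 0.922 of that number with r = −0.323 across genes, and against the trend with probe GC content, whose removal left 0.756 with r = −0.349. Still open is an exchange of the group labels on slide 2. Exchanging them left 0.000561 of the number, namely 2 genes, and then 1223 genes and 9 lists passed between the groups. These counts cannot decide the question. With exchanged labels the slide difference tests the treatment effect shared by the slides, and the group difference tests the slide difference as labelled. The exchange changes the sign of slide 2 by construction, so the counts may as well reflect cultures or handling that differed between the slides. The slide 2 fold changes were smaller, with an SD of 0.290 against 0.477. ANKRD36 and FOSB, which had the same direction on both slides as labelled, would have opposite directions under exchanged labels.

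The number of genes called gives no ground to exclude chance, as 3 of the 35 splits of the 8 arrays gave at least the 1 gene of the real split. These were the real split, slide 1 against slide 2 with 1 gene, and the split with the groups exchanged on slide 2, which gave 1223, the highest, and points to a structure of the samples. With slide as a block 0 genes passed in limma, with 1352 at an unadjusted p under 0.05. For the number of gene lists, 33 of the 35 splits gave at least the 1 list of the real split, with 16 as the highest of the others, so chance was not excluded there either.

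At an unadjusted p under 0.05 more genes were lower than higher with canagliflozin, by a ratio of 4.07, and of 2.32 to 7.88 without 1 array. Over all splits chance was not excluded, since 6 of 35 gave as large an excess, with 722 for the real split, 940 as the highest of the others and 936 for slide 1 against slide 2. Among the 18 splits with 2 arrays of each slide on either side the real one was the highest and the next gave 491, but 18 splits are too few for a share under 0.05. The data argue against array brightness and scaling as the whole cause, since quantile normalization left a ratio of 3.58 (1.67 to 6.16 without 1 array), never under the 1.5 that this cause was taken to need. The trend with probe GC content cannot be told apart from a real excess, since its removal left 2.26 (1.08 to 4.20), each range being lowest without canagliflozin replicate 4 and highest without control replicate 2, and no biological explanation was tested.

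The ribosomal protein list was higher with canagliflozin over all 8 arrays at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.788). The data argue against the trend with probe GC content, whose removal left 0.891 of the median (adjusted p = 2.56e-06). Array brightness and scaling remain a candidate explanation, since quantile normalization left 0.0834 of the median (adjusted p = 0.413), although it would also remove a real shift shared by the brightest genes. Random lists drawn within 100 places of each member in mean level had a median of 0.16, with 95% between 0.12 and 0.20. The ribosomal list stood at percentile 76.0 among 10000 of them. Ribosomal genes were not kept out of the draws, so the list was partly compared with itself and this decides nothing. The 10th and brightest decile of all genes had a median of 0.024, but it is no like comparison. Its median level was 4.22, while the ribosomal members had a lowest mean level of 4.28 and a median of 6.58. No biological explanation was tested.

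By list, the median slide 2 minus slide 1 difference was 0.95 for cholesterol synthesis and uptake, 0.39 for fatty acid synthesis, 0.026 for the integrated stress response, 0.60 for NRF2 targets, 0.74 for extracellular matrix, 0.53 for the TGF-beta response, −0.44 for G2/M, −0.059 for S phase and 1.22 for fibroblast and pericyte markers. Under the rule for naming genes, those with the largest positive differences were RHOJ with 2.58, TCF7L1 with 2.33, LPHN2 with 2.02, BMP4 with 2.01, ARL15 with 1.95, CAMK1D with 1.90, FLI1 with 1.90, LMO7DN with 1.88, HIST1H1A with 1.84, MFAP4 with 1.82, VIT with 1.82 and STON1-GTF2A1L with 1.81. The largest negative differences under that rule were −2.46 for KLHL23, −2.32 for INHBE, −2.31 for RPS6KA1, −2.30 for AURKB, −2.28 for TSPAN15, −2.27 for BEX4, −2.18 for NUP210, −2.12 for MAPK13, −2.08 for B3GNT4 and −2.06 for SCNN1A.

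A single array stood apart from the other 3 of its group, by Dixon's ratio of the gap to the range, in 6 of the 210 sets of 4 values tested, where chance gives about 10.5. In canagliflozin these were SCD with a ratio of 0.843 (replicate 1 at −0.27, the others 0.16 to 0.24), ZNF501 with 0.879 (replicate 3 at −3.82, the others −3.72 to −3.71), TMEM97 with 0.855 (replicate 4 at 2.38, the others 2.06 to 2.10) and ACSL1 with 0.895 (replicate 2 at −1.17, the others −1.46 to −1.43). In control they were LDHA with 0.857 (replicate 2 at 3.51, the others 3.73 to 3.77) and HIST1H1E with 0.891 (replicate 1 at 2.27, the others 1.90 to 1.94).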

How the results depend on the processing

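The floors at 0.5 and 2 times the main floor, the removal of the trend with probe GC content and the number of genes with a slide difference were chosen after the data were seen. The call of 1 gene, lower with canagliflozin, held with median scaling, quantile normalization, the deposited value table, the filter on all 8 arrays, trended and robust variance, outlier spots missing, both floors, GC removal, the 1.5-fold threshold and the adjusted threshold of 0.1. It was lost, to 0 genes, with normexp, no filter, the mean of probes, slide or replicate number as a block, and slide 2 alone. For ANKRD36 the fold change was −0.71 with normexp (adjusted p = 0.912) and −0.79 with the mean of its probes (adjusted p = 0.156), and without a filter more genes were tested (adjusted p = 0.0708). Over all alternatives its adjusted p lay between 0.0245 and 0.912. Slide 1 alone gave 1680 genes, 970 higher and 710 lower, but 1148 higher and 1630 lower with median scaling, 893 and 302 with GC removal, and 0 genes with the floor at 2 times or normexp. Without 1 array the count was 0 to 12, the 12, all lower, without canagliflozin replicate 3 and 0 without any of the others. The single list called became 0 with quantile normalization, the value table and an estimated correlation, 4 with normexp, 3 with the mean of probes, 2 with the replicate block, 5 on slide 1, 15 on slide 2 and 4 with GC removal, and 1 to 8 without 1 array. The highest of these were 8 and 7 without canagliflozin replicates 1 and 2, and 2, 4 and 3 without canagliflozin replicate 4 and control replicates 1 and 2. The replicate numbers showed no sign of pairing the samples beyond the slide. Across genes, deviations from the group mean correlated at −0.113, −0.446, −0.208 and −0.378 between canagliflozin and control samples of the same number. Pairs of the same slide with different numbers gave −0.007, −0.265, 0.035 and −0.319. The number of genes with a slide difference was 0 with normexp, 423 to 4763 without 1 array, and 2697 to 3617 with the other settings. Under normexp the median size of the difference in the 3568 genes was 0.62 against 0.90, and its SE 0.27 against 0.20. The cause was not tested for the other changes. On slide 1 alone the medians of cholesterol synthesis (−0.45), G2/M (0.19) and ribosomal proteins (−0.0018) reversed, and on slide 2 alone those of fatty acid synthesis (0.24), NRF2 targets (0.38), extracellular matrix (0.33) and fibroblast and pericyte markers (0.46). Of 1935 values of single genes 14 changed sign, and of 804 list medians 99 did, among them the 7 just given. Of the 14, 10 came with slide 2 alone, where 81 genes were counted. Genes named for their slide difference were not among the 1935, and many of those counted were named for a small p, which favours a stable sign. The share of genes at an unadjusted p under 0.05 that were lower was 80.3%, and 69.4% after GC removal and 90.9% with normexp. Signal over background limits HYDIN, FOSB, GOLGA6C, ZNF501, PPFIA4 and TGFBR1, which were not well above background on every array.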

Other observations

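The test of epithelial and mesenchymal genes was chosen after the slide difference was seen.

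Genes of mesenchymal cells differed between the slides. In a list of 30 such genes, all measured, the median log2 fold change was −0.64 on slide 1 and 0.47 on slide 2, a median difference of 1.22. By the slide by treatment test 22 members passed as higher on slide 2 and 0 as lower (camera adjusted p = 1.78e-08 over both lists, and adjusted p = 0.199 with an estimated correlation). Many members, such as COL1A1, COL3A1, PDGFRB, THY1 and POSTN, are also in the matrix or the fibroblast and pericyte list. The result is thus in part the difference already seen in those lists and no independent support for it. A list of epithelial junction and identity genes, with 21 of 30 measured, had a median difference of 0.119 (camera adjusted p = 0.850). Among them 2 members passed as higher on slide 2 and 2 as lower. A difference between the cultures of the slides along an epithelial to mesenchymal axis would need the epithelial list to move the other way. Its median moved the same way as the mesenchymal one, so this condition was not met. The move was small beside the median difference of 0.16 over all genes, and members went both ways. A contribution of such a difference is therefore not excluded.

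On control replicate 1, 100 spots lay at least 2 log2 units below the median of the arrays, and 94 of them had another such spot within 3 rows or columns. On canagliflozin replicate 2, 28 spots lay as far above it, and 23 had another within that distance. Fold change and GC content of the probe had a correlation across genes of 0.283 over all arrays, 0.265 on slide 1 and 0.0236 on slide 2.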
